A study of Rattus norvegicus with 4 samples.

How the data were processed

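The samples were 4 arrays of total RNA from rat adrenal medulla, 2 from unstressed rats and 2 from rats immobilized for 2 h. The groups were taken from the descriptions the submitters gave for each sample. Replicates were numbered in accession order, which pairs nothing between groups. The deposited table holds 1 linear intensity per probe set and array, with 31099 rows. The method by which the authors summarised probes into these intensities is not given in the sources used here. From the values, each deposited column had been scaled to the same trimmed mean, 2501 after leaving out 2% of values at each end, with a spread over the 4 arrays of 0.00572%. The rule fixed before the data were examined kept the deposited scaling where trimmed means differed by no more than 5%, so no further normalization was applied. No detection calls were used, and low intensities were set only against the readings of the array's 27 Bacillus control probe sets. There were 0 unused sample columns.

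The 57 control probe sets were left out, which leaves 31042. Intensities were turned into log2(intensity + 16), so every fold change is on that scale and understates the change of dim genes. Probe sets with a mean log2 value under the 40th percentile, an intensity of about 543.8, were not tested, which removed 12417 and left 18625. The filter uses the mean over all 4 arrays. Genes were named from GEO's annotation of the platform, updated by Entrez identifier through a gene table of the GRCr8 assembly, which was otherwise used only to find neighbouring genes. A single symbol was listed for 20826 probe sets, several for 436 and none for 9780, and only the first kind was named. Of these, 20758 were found in the gene table and 0 symbols changed. The probe sets of Gapdh and Actb outside the controls name several genes, so the array's own control probe sets are reported for them. A gene was represented by its probe set with the highest mean log2 value.

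The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend), two-sided, with Benjamini-Hochberg adjustment over all tested probe sets and a threshold of 0.05. The prior contributed 4.81 degrees of freedom, for 6.81 in all. SEs and 95% intervals are those of the moderated fit. With 2 arrays against 2, an exact two-sided permutation test cannot give a p below 0.33, so no such test is reported. On simulated data with the means of the same 18625 probe sets and variances drawn from the fitted prior, the fit called 25 of 100 changes of 2-fold and 89 of 100 changes of 4-fold, and 4.8% of its calls were false. The simulated noise was independent between probe sets and leaves out errors that probe sets share on an array. That percentage is therefore not the rate of false calls in the data. With 125 calls in the simulation against 5799 in the data, its threshold was the stricter, and 1012 of 1092 probe sets with a log2 change within 0.1 of 1 were called in the data.

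Before the data were examined, 17 pathway lists and 9 lists of cell type markers were fixed. The 23 lists with at least 5 tested genes were tested with limma's camera at a preset correlation between genes of 0.01, Benjamini-Hochberg adjusted over the 23. Camera with an estimated correlation, which limma tests on the 2 residual degrees of freedom and not on a number set by the genes, and fry served as alternatives. A synonym match put Sprr1a, an unrelated gene, in place of Spr in the catecholamine list; it lay under the filter level and entered only the test with no filter. List members were also adjusted over the list alone. Genes to name were drawn by a rule fixed at the same time: the 12 largest rises and the 12 largest falls among genes past the threshold whose groups did not overlap, up to 6 called members of each list, the 2 largest changes of a list with no call, and the controls Th, Dbh, Pnmt, Fos, Egr1, Cyp11b1 and Cyp11a1. The rule gave 120 genes, called the named genes below, and not all of them appear in the text. Genes with bare locus names were skipped. Other members of the lists are named as examples or as values, and were chosen after their values were seen. The gene families in the closing observations were chosen after the values were seen as well.

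The alternatives were quantile normalization, median centring of each array, offsets of 1 and 64, no filter and a filter at the 60th percentile, eBayes without the trend and with robust estimation, leaving out each array in turn, a threshold of 0.10, 1 probe set per gene, the mean of a gene's probe sets, and the list tests named above. With an array left out, the lone array of its group was assumed to vary like the other group, so the spread came from the pair of that other group alone. Counts of calls with an array left out therefore depend on which pair remained. An offset of 256 and the omission of probe sets at or above the 99th percentile of level were added after the data were seen. Plots were drawn with matplotlib 3.10.9.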

Results

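Gene expression was measured in the adrenal medulla of rats, the inner part of the adrenal gland whose chromaffin cells make and release adrenaline and noradrenaline. Total RNA was hybridised to 4 single-colour oligonucleotide arrays. The arrays fall into 2 groups of 2: unstressed rats and rats immobilized for 2 h, immobilization being a standard form of stress in rodents. The comparison asks which transcripts differ in the adrenal medulla after 2 h of immobilization. Whether it was given once or repeatedly, and how soon afterwards tissue was taken, is not stated in the descriptions used here. The labels do not say whether the arrays of a group come from separate animals or from pools, so the p-values measure the spread between these samples, which may be technical. The number of arrays limits the precision of every value.

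With the control probe sets left out, the table held 31042 probe sets, the groups of short probes that each report on a transcript. Median intensities were 955 and 911 on the unstressed arrays and 864 and 827 on the immobilized arrays. The arrays differed at the bright end. The 99th percentile of intensity was 30002 and 31739 on the unstressed arrays, 36447 on immobilized 1 and 30549 on immobilized 2. The highest intensity was 70582 and 75600 on the unstressed arrays, 74591 on immobilized 1 and 52133 on immobilized 2. Across the 18625 tested probe sets, Pearson's r was 0.967 between the unstressed arrays and 0.981 between the immobilized arrays, against 0.856 to 0.871 between arrays of different groups. These correlations run across probe sets, which are not independent replicates. The median absolute log2 difference was 0.21 between the unstressed arrays, 0.17 between the immobilized arrays and 0.40 to 0.43 between groups. The Actb control of the array, the gene for beta-actin, had 3' probe set intensities of 46021 and 50315 in the unstressed group and 58405 and 44279 in the immobilized group. The Gapdh control, for a glycolytic enzyme, had 49602 and 50730 against 51495 and 42070. The 3' over 5' ratio of the Actb control, which rises as RNA degrades, was 2.15 and 1.90 in the unstressed group and 1.99 and 1.62 in the immobilized group.

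The 12 genes with the largest log2 rises held the transcription factor genes Fosb, Nr4a3, Atf3 and Maff and the peptide genes Calca and Nts. Fosb, a partner in the AP-1 transcription factor, rose by 7.42 ± 0.26 on the log2 scale (SE, n = 2 per group). Its mean intensity went from 39.9 ± 7.73 to 9683 ± 2277 (SD), and the unstressed level was not shown to lie above background, since the 27 control probe sets for Bacillus transcripts read 2.18 to 257. Nr4a3, an orphan nuclear receptor, rose by 5.84 ± 0.15, or 57.3-fold, from 601 to 35308, and its 3 tested probe sets ranged from 2.20 to 5.84. Calca, which encodes calcitonin and calcitonin gene-related peptide, rose by 5.57 ± 0.21, from unstressed readings of 117 and 114 that lie within the range of those controls. With each gene represented by its brightest probe set, the largest fall was that of Shpk, the gene for sedoheptulokinase, whose log2 change was -3.24 ± 0.21, 9.44-fold lower.

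In all, 2180 probe sets rose and 3619 fell at a Benjamini-Hochberg adjusted p under 0.05 in limma, together 31.1% of those tested. By gene, with 1 probe set each, 1156 of 10320 genes rose and 2251 fell. The groups did not overlap at any of the 5799 called probe sets, nor at 12637 of all tested probe sets, or 67.8%, where chance gives 33.3%. Non-overlapping differences of at least 2-fold numbered 1176 upward and 1455 downward. The rises were the larger changes: 346 called probe sets rose and 101 fell by at least 4-fold, and 142 rose and 5 fell by at least 8-fold. The split between rises and falls depended on the scaling. Of all calls 37.6% were rises with the deposited scaling, 44.9% after quantile normalization (2581 rose and 3171 fell) and 53.1% after centring each array on its median (2897 rose and 2560 fell). Median centring moved the median log2 change of all tested probe sets from -0.12 to 0.02. Without the array immobilized 1 the counts were 973 and 1088, and without immobilized 2 they were 785 and 893.

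**Figure D1:**
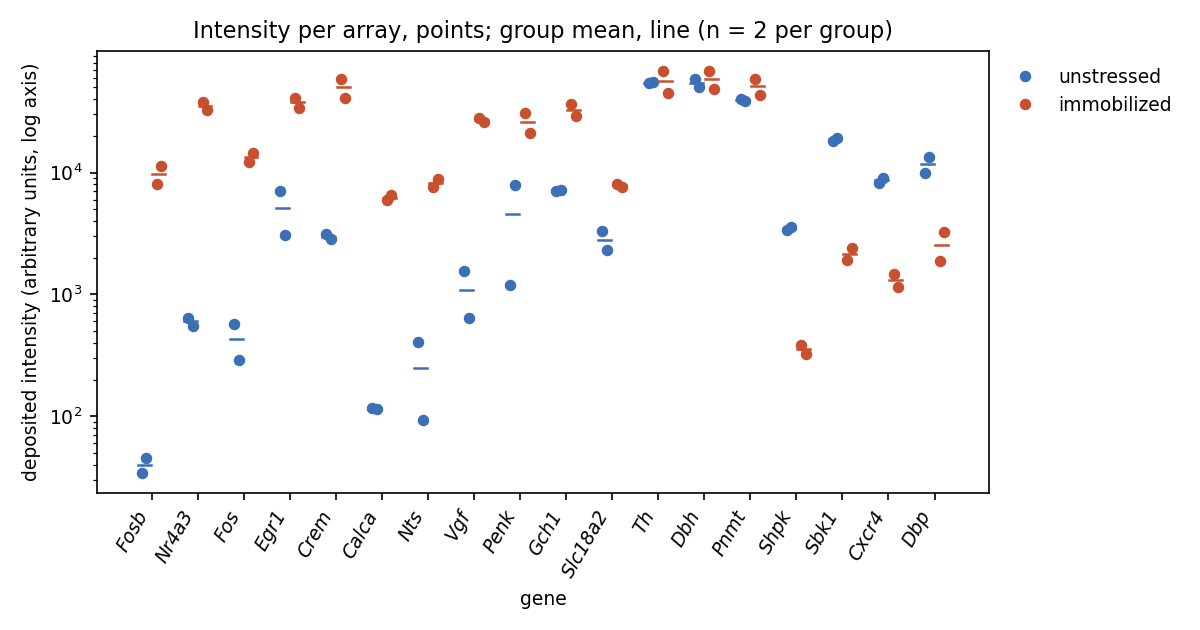
Deposited intensity of named genes on each of the 4 arrays, on a log axis in arbitrary units, with points for arrays and short lines for group means (n = 2 per group). Fosb lies at a mean of 39.9 in the unstressed group and 9683 in the immobilized group, while Th lies at 54841 and 56515.

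The 12 largest rises, after Fosb, included Iqub (log2 change 7.27 ± 0.26), Fam110c (5.64), Phlda1 (5.61), Nts (5.26 ± 0.57), Atf3 (5.24), Maff (5.13), Adamts4 (5.08) and Ackr3 (5.08). Iqub encodes a protein of motile cilia, Adamts4 a protease that cleaves proteoglycans, and Ackr3 a scavenging chemokine receptor. Vom2r53, a member of the vomeronasal receptor family, rose by 5.0. Their adjusted p in limma lay between 1.86e-05 for Nr4a3 and 0.00127 for Nts. The unstressed readings of Iqub, 45.7 and 68.4, also lie within the range of the Bacillus controls, as do those of Atf3 and Vom2r53 and 1 unstressed reading each of Fam110c, Phlda1, Nts and Maff. Their baselines were thus not shown to lie above background, and their sizes and ranks depend on the offset added before the logarithm: with offsets of 1 and 64 in place of 16 the log2 change of Fosb was 7.88 and 6.53. At 64 Iqub stood above it, at 6.54. An offset 4 times larger again, added after the data were seen, gave Fosb 5.05 and Iqub 5.19, both below Nr4a3 at 5.37.

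Among the largest falls, Sbk1, a serine/threonine kinase gene, changed by -3.12 and Smtnl2 by -3.03. Arhgef40 changed by -3.0, Tmem86a by -2.98 and Rasal1, a regulator of Ras, by -2.82. Cxcr4, the receptor of the chemokine Cxcl12, fell from a mean intensity of 8626 to 1309, a log2 change of -2.71, and its 3 tested probe sets ranged from -3.29 to -2.58. Rpp25, Zfp395, Macir and Hykk had log2 changes of -2.76, -2.62, -2.60 and -2.58. Pex26, a peroxisome biogenesis gene, had a change of -2.75 ± 0.75 with an adjusted p of 0.0324 in limma, which was 0.0528 without the intensity trend and 0.0606 without the filter on dim probe sets. Its reading on immobilized 1, 70.6, lies within the range of the Bacillus controls, as does that of Hykk, 225.

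Of 31 tested immediate early genes, those switched on without new protein synthesis, 29 rose, 0 fell and 2 did not pass the test, and the counts adjusted over the list alone were the same. Their median log2 change was 2.33 (camera adjusted p = 1.13e-22, and adjusted p = 0.178 with an estimated correlation). Fos rose by 4.97 ± 0.31, Egr1 by 2.99 ± 0.35, Junb by 3.25 ± 0.14 and Nr4a1 by 3.13 ± 0.16. Jun and Jund had changes of 0.05 and -0.09 and did not pass. The probe sets of Jun disagreed, since a dimmer one had a log2 change of 0.98.

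Of 15 genes responsive to cAMP and its transcription factor CREB, 13 rose and 0 fell, also when adjusted over the list alone, with a median of 3.55 (camera adjusted p = 1.21e-12, and adjusted p = 0.178 with an estimated correlation). Crem, which encodes an inducible cAMP repressor, rose by 4.04 ± 0.19, from a mean intensity of 2987 to 50105, and its 6 tested probe sets ranged from 2.13 to 5.35. Inhba, a subunit of activin, rose by 4.79, Ptgs2, the inducible cyclooxygenase, by 4.59, Nfil3 by 4.39 and Bdnf, a neurotrophin, by 4.23. The unstressed readings of Inhba, Ptgs2 and Bdnf lie within the range of the Bacillus controls, so the sizes of these 3 rises are not exact, and so does 1 reading of a dimmer Crem probe set. Vip and Ppargc1a did not pass, at 0.60 and -0.59, though Vip did without unstressed 1 (1.14, adjusted p = 0.00911 in limma). Of 15 feedback inhibitors of MAP kinase and growth factor signalling, 13 rose and 0 fell, the same when adjusted over the list alone, with a median of 1.53 (camera adjusted p = 4.47e-10, and adjusted p = 0.189 with an estimated correlation). Without immobilized 2 the list had 8 rises. The phosphatase genes Dusp14, Dusp5 and Dusp1 rose by 3.09, 2.89 and 2.14, and Spry2 by 2.89. Per1, Rgs2, Errfi1 and some others stand in more than 1 list.

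In the catecholamine pathway 3 genes rose. Gch1, which makes the first intermediate of the tetrahydrobiopterin cofactor of tyrosine hydroxylase, rose by 2.19 ± 0.15, or 4.56-fold. Gchfr, which encodes its feedback regulator, rose by 2.41 ± 0.16, or 5.30-fold. Slc18a2, a vesicular monoamine transporter, rose by 1.5 ± 0.19, or 2.83-fold. Th, the rate-limiting enzyme, had a log2 change of 0.01 ± 0.22 with a 95% interval of -0.51 to 0.53, and Dbh, which makes noradrenaline, had 0.09 ± 0.20. Pnmt, which makes adrenaline, had 0.36 ± 0.18 with an adjusted p of 0.171 in limma, but 0.41 with an adjusted p of 0.00609 after quantile normalization and 0.57 with an adjusted p of 0.0448 without immobilized 2. Among others that did not pass, Slc18a1, the other vesicular monoamine transporter, had 0.60, and the cofactor genes Pts and Qdpr had -0.32 and -0.07. Slc18a1 passed without unstressed 1 (0.99, adjusted p = 0.0048 in limma) and Pts without unstressed 2 (-0.58, adjusted p = 0.0332). Of 14 tested members 3 rose and 0 fell, likewise when adjusted over the list alone, with a median of 0.10 (camera adjusted p = 0.017, and adjusted p = 0.684 with an estimated correlation). The list's camera adjusted p was 0.186 without immobilized 1. Th, Dbh and Pnmt lay in the top 0.5% of levels, where the SD of the log2 change over 156 probe sets was 0.165, against 0.713 between the 90th and 95th percentiles.

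**Figure D2:**
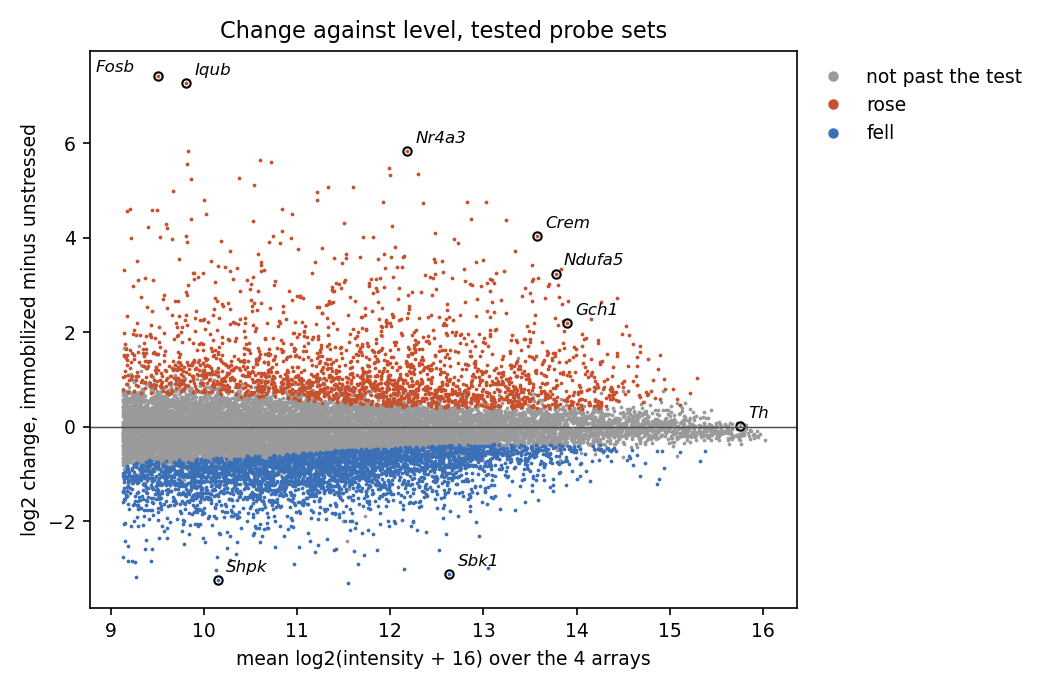
Log2 change, immobilized minus unstressed, against the mean log2(intensity + 16) over the 4 arrays, 1 point per tested probe set, coloured by whether it rose, fell or did not pass the test. Changes narrow at the bright end, where Th lies at 0.01, while Fosb and Iqub stand at 7.42 and 7.27.

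Of 20 tested genes for neuropeptides, granins and prohormone processing, 7 rose and 0 fell, or 8 and 0 adjusted over the list alone, with a median of 0.43 (camera adjusted p = 4.51e-05, and adjusted p = 0.538 with an estimated correlation). Without unstressed 1 the list had 11 rises. Besides Calca and Nts, the gene for neurotensin, Vgf rose by 4.74 ± 0.36, Stc1 by 2.65 ± 0.16, Gal, the gene for galanin, by 1.46 ± 0.19 and Npy by 0.80 ± 0.23. The call on Npy was lost without unstressed 2, immobilized 1 or immobilized 2 (adjusted p = 0.181, 0.193 and 0.0715 in limma). Penk, the gene for proenkephalin, rose by 3.04 ± 0.76 (adjusted p = 0.0241 in limma), and its unstressed arrays read 1190 and 7891. Its adjusted p was 0.159 without immobilized 1, 0.12 without immobilized 2 and 0.0542 with the robust variance model. The granin genes Chga, Chgb and Scg2 had changes of -0.09, 0.05 and 0.08 and did not pass, and they too lay in the top 0.5% of levels. Of 17 genes of the exocytosis machinery 3 rose and 1 fell, also when adjusted over the list alone (median 0.21, camera adjusted p = 0.055). That p was 0.00399 without unstressed 1 and 0.0189 without immobilized 2. Sv2c, a vesicle glycoprotein gene, rose by 1.97 ± 0.27. The calls on Syt4, Snap25 and Rab3a (1.38, 0.84 and -0.77) were lost without immobilized 1 (adjusted p = 0.0835, 0.187 and 0.117 in limma) and without immobilized 2 (0.0876, 0.0894 and 0.177), which left 1 rise and 0 falls. Snap25, at 0.52 without unstressed 2, and Rab3a, at -0.52 without unstressed 1, lost their calls there too. The call on Snap25 was also lost after quantile normalization, without the filter and without the trend (adjusted p = 0.0541, 0.0567 and 0.0626 in limma). Of 15 genes for nicotinic receptors and excitability channels 1 rose and 1 fell, the same over the list alone (median -0.04, camera adjusted p = 0.482). The counts were 5 and 1 without unstressed 1, 1 and 3 without unstressed 2, and 0 and 1 with either immobilized array left out. The potassium channel gene Kcnh2 had a change of -1.34 ± 0.18. The nicotinic subunit genes Chrna3 and Chrnb4 had changes of -0.16 and -0.43 and did not pass, though both did without unstressed 2 (adjusted p = 0.0443 and 0.0231).

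Of 18 glucocorticoid responsive genes 10 rose and 3 fell, the same when adjusted over the list alone, with a median of 0.70 (camera adjusted p = 4.58e-05, and adjusted p = 0.192 with an estimated correlation). The members did not move one way. The cell cycle inhibitor Cdkn1a rose by 3.13, Ddit4 by 2.44, Cebpd by 2.14, and Fkbp5 and Sgk1 each by 1.11, while Tsc22d3 had a change of -0.45, Pdk4 of -1.10 and Angptl4 of -1.11. A dimmer probe set of Pdk4 had a change of -0.06. These 3 falls were lost without immobilized 1 (adjusted p = 0.0877, 0.0808 and 0.122 in limma), and those of Tsc22d3 and Pdk4 also without immobilized 2 (0.12 and 0.0604). Tsc22d3 was lost without unstressed 2 as well (0.132). The list then had 9 rises and 0 falls without immobilized 1, and 9 and 1 without immobilized 2. Cdkn1a, Ddit4 and Cebpd are also known to respond to other stresses. Of 16 clock genes 5 rose and 5 fell, the same over the list alone (median -0.16, camera adjusted p = 0.638), against 3 and 2 without immobilized 1 and 2 and 4 without immobilized 2. Per1 rose by 1.58 and Rora by 1.17, whereas Dbp, an output gene of the clock, changed by -2.22 ± 0.27 and Tef by -1.43.

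Of 18 inflammatory and NF-kB responsive genes 11 rose and 2 fell, or 13 and 2 adjusted over the list alone, with a median of 0.81 (camera adjusted p = 6.41e-06, and adjusted p = 0.192 with an estimated correlation). Without immobilized 1 there were 8 rises and 1 fall, and without immobilized 2 there were 5 and 1. Ccl2, a monocyte chemokine, rose by 2.91 ± 0.22, Icam1 by 2.37 and Nfkb1 by 1.62. The interferon responsive genes Irf1 and Cxcl10 changed by -1.40 and -1.13, and the call on Cxcl10 was lost without immobilized 1 or immobilized 2 (adjusted p = 0.0749 and 0.154 in limma). Of 19 genes for heat shock proteins and chaperones 9 rose and 0 fell, also over the list alone, with a median of 0.46 (camera adjusted p = 1.06e-04, and adjusted p = 0.538 with an estimated correlation). The rises numbered 5 without immobilized 1. Hspb8 rose by 3.02 ± 0.15, Hspa1a, the inducible Hsp70, by 2.88 ± 0.16, Hspa4l by 2.40 and Bag3 by 1.84, while Hsp90ab1 and Hspd1, the latter at percentile 99.97 of level, did not pass at -0.12 and -0.25. Of 22 genes of the unfolded protein response 5 rose and 2 fell, the same over the list alone, with a median of 0.14 (camera adjusted p = 0.0272, and adjusted p = 0.519 with an estimated correlation). Atf4 rose by 1.57 and its target Trib3 by 2.28, but Ddit3 and Herpud1 each changed by -0.97. The call on Ddit3 was lost without immobilized 2 (adjusted p = 0.0534 in limma) and that on Herpud1 without immobilized 1 (0.0751). The call on this list was lost after quantile normalization (camera adjusted p = 0.0848), without unstressed 1 (0.0694) and without immobilized 1 (0.0717). Its counts were 3 rises and 1 fall with either immobilized array left out.

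Of 16 genes of cholesterol biosynthesis 5 rose and 2 fell, also over the list alone, with a median of 0.27 (camera adjusted p = 0.00937, and adjusted p = 0.344 with an estimated correlation). The counts were 4 and 0 with either immobilized array left out. Idi1 rose by 2.03 ± 0.17, Insig1, a feedback regulator of the pathway, by 1.78 and Acat2 by 1.61. Fdft1 changed by -1.07, with a dimmer probe set at -1.17, and Lss by -0.62. Neither fall stayed past the threshold with either immobilized array left out. Of 17 genes of hypoxia and glycolysis 5 rose and 0 fell, the same over the list alone, with a median of -0.06 and a mean of 0.27 (camera adjusted p = 0.133, but 0.0455 without unstressed 2 and 0.0316 without immobilized 2). Only 2 rose with either immobilized array left out, and 4 rose and 1 fell without unstressed 1. Pfkfb4, a regulator of glycolytic flux, rose by 2.04. The other rises were Pfkfb3 at 2.24, P4ha1 at 0.76, Ldha, an enzyme gene of glycolysis, at 0.63 and Slc2a1 at 0.50. Dimmer, untested probe sets of Pfkfb3 had changes of 0.24 and 0.09. The call on Slc2a1 was lost without the filter and without the trend (adjusted p = 0.0524 and 0.0581 in limma). Pgk1, Tpi1 and Aldoa, which also act in the pathway itself, did not pass at 0.10, 0.12 and -0.07, Aldoa at percentile 99.83 of level. Of 28 genes of oxidative phosphorylation 1 rose and 1 fell, or 1 and 0 over the list alone (median -0.07, mean 0.07, camera adjusted p = 0.555). Leaving out unstressed 2 gave 2 and 0, and leaving out either immobilized array gave 1 and 0. The riser was Ndufa5, a complex I subunit, at 3.24 ± 0.18, from a mean intensity of 4581 to 43345. Of 13 genes of p53 and growth arrest 5 rose and 3 fell, the same over the list alone (median 0.03, camera adjusted p = 0.127, but 0.0418 without unstressed 2). Gadd45a rose by 2.88, and Ccng2 and Sesn1 changed by -1.80 and -1.67. None of 40 ribosomal protein genes passed, so 0 rose and 0 fell, also over the list alone, and 1 had an unadjusted p under 0.05, with a median of -0.06 (camera adjusted p = 0.574). Rpl21 passed as a rise after quantile normalization (0.26, adjusted p = 0.0415 in limma), after median centring (0.53, adjusted p = 0.0287) and without probe sets at or above the 99th percentile of level (0.39, adjusted p = 0.0325). Leaving out an array gave this list opposite directions, lower without immobilized 1 (camera adjusted p = 0.0139) and higher without immobilized 2 (0.0016).

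**Figure D3:**
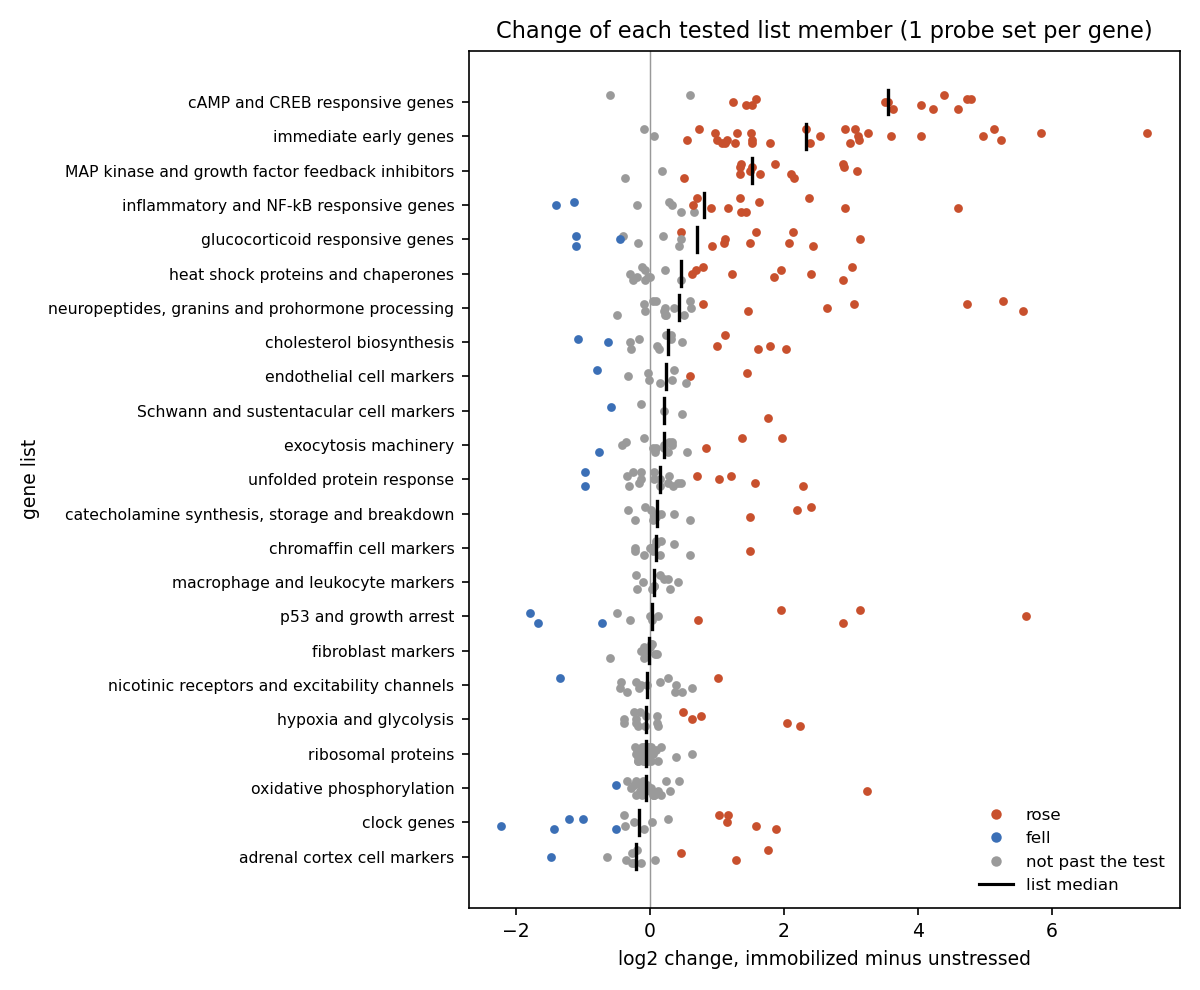
Log2 change, immobilized minus unstressed, of each tested member of the 23 gene lists, 1 point per gene, coloured by whether it rose, fell or did not pass the test, with a black line at each list's median. The list of cAMP and CREB responsive genes has the highest median, 3.55, and that of adrenal cortex cell markers the lowest, -0.21.

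None of the 6 tested lists of markers for cell types that the dissected tissue could hold passed camera. That test compares the groups and does not show that the mix of cell types was the same on each array. Of 13 chromaffin cell markers 1 rose, which was Slc18a2, and 0 fell, also over the list alone (median 0.08, camera adjusted p = 0.133). That p was 0.0439 without unstressed 1, where 3 rose, and 0.000803 without immobilized 2, where 2 rose. Of 12 adrenal cortex markers 3 rose and 1 fell, or 3 and 2 over the list alone (median -0.21, camera adjusted p = 0.638). The counts were 2 and 2 without unstressed 1, 1 and 3 without immobilized 1, and 2 and 0 without immobilized 2. Scarb1, a lipoprotein receptor, rose by 1.76 ± 0.20, Mrap by 1.29 and Nr5a1 by 0.47. The call on Nr5a1 was lost after quantile normalization and without the filter (adjusted p = 0.0657 and 0.0702 in limma). Nr0b1, a repressor of steroidogenic genes, changed by -1.48 ± 0.27, and its adjusted p was 0.0767 without immobilized 1 and 0.0622 without immobilized 2. The steroidogenic enzyme genes did not pass: Cyp11b1 had a change of -0.64 (adjusted p = 0.0591 in limma) and Cyp11a1 of -0.35 (adjusted p = 0.209). Cyp11a1 lay at percentile 99.93 of level, where changes were narrow. After quantile normalization both passed, at -0.76 (adjusted p = 0.0123) and -0.25 (adjusted p = 0.0249), and Cyp11b1 also did without unstressed 1, at -0.95 (adjusted p = 0.00356). The cortical transcripts were abundant in both groups, with mean intensities of Cyp11b1 of 29515 ± 9032 and 18533 ± 143 (SD). The unstressed arrays differed in this gene, at 23128 on unstressed 1 and 35901 on unstressed 2. Since cortical transcripts were abundant in this RNA, the arrays cannot tell whether rises in the other lists came from chromaffin or cortical cells.

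Of 5 Schwann and sustentacular cell markers Gfap rose by 1.76 and S100b changed by -0.59, the same over the list alone (camera adjusted p = 0.355). Of 10 endothelial markers 2 rose and 1 fell, the same over the list alone (camera adjusted p = 0.127), with Flt1 at 1.45 and Kdr, another receptor of vascular endothelial growth factor, at -0.79. The rise of Flt1 rests on 1 of its 3 probe sets, since the others had changes of 0.14 and 0.06. The calls on S100b and Kdr were lost without immobilized 1 (adjusted p = 0.0993 and 0.148) and without immobilized 2 (0.135 and 0.0768), and that on Flt1 without immobilized 1 (0.0554). The endothelial counts were 0 and 0 without immobilized 1 and 1 and 0 without immobilized 2, and 2 Schwann markers rose without unstressed 1. None of 11 macrophage and leukocyte markers and none of 10 fibroblast markers passed, also over the lists alone (camera adjusted p = 0.251 and 0.728), their medians were 0.06 and -0.02, and 1 gene of each list had an unadjusted p under 0.05. C1qb, Ptprc, Fbln1 and Col3a1 had changes of 0.42, 0.30, -0.60 and -0.13. C1qb passed after median centring (0.56, adjusted p = 0.022 in limma), with the filter at the 60th percentile (0.046), with the mean of probe sets (0.0417) and without unstressed 2 (0.0477), where Col3a1 passed too, at -0.50 (0.0378). Too few markers of erythroid cells (3), adipocytes (2) and granulocytes (0) were tested for a list test. The erythroid genes Hba-a3 and Alas2 had changes of 0.40 and 0.30, and the adipocyte genes Cfd and Pnpla2 of 0.51 and 0.04, and none passed, though Cfd did without unstressed 2 (0.76, adjusted p = 0.0322 in limma).

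Camera compares a list with all other genes, whose median change was below 0, and its direction was upward for each of the 23 lists. For the lists of nicotinic receptors and channels, hypoxia and glycolysis, oxidative phosphorylation, clock genes, ribosomal proteins, cortex markers and fibroblast markers the median was below 0 although the test pointed upward. Of the 10 lists that passed camera, 0 did so with an estimated correlation, a version that also rests on only 2 residual degrees of freedom. The estimate itself was -0.0291 for the cAMP list and -0.026 for the glucocorticoid list, below the preset 0.01. In fry, which tests whether the genes of a list move on balance one way, 6 of those 10 passed, as did the p53 list (adjusted p = 0.0406). The other 4, on catecholamines, neuropeptides, heat shock proteins and the unfolded protein response, had fry adjusted p of 0.236, 0.0666, 0.0666 and 0.0666.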

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

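The test of RNA integrity, the look at hybridisation controls and the fit with the gap in level were chosen only after the results they bear on were seen, and so was the reading of the slope test as undecided for abundant transcripts.

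A control probe set outside the main comparison, that for 5S ribosomal RNA, was higher in the immobilized group by 1.03 on the log2 scale. It read 2465 and 2775 on the unstressed arrays and 5346 and 5391 on the immobilized arrays. It was the only 1 of 27 controls above the filter level that was at least 1.5-fold higher on both immobilized arrays, while the 3 Hexokinase controls, of which only the 3' lay above that level, were lower on both (3' -0.85, 5' -0.77, middle -2.16).

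Th, Dbh and Chga lie at percentiles 99.92, 99.93 and 99.85 of level and differed little between groups. Among 10 genes whose brightest probe set lies at or above the 99th percentile and whose dimmer probe set was called, the bright change was 0.266 times the dim one (95% interval 0.107 to 0.424), against 0.702 (0.658 to 0.746) in 394 pairs from the 80th to 95th percentiles, a difference of -0.436, and leaving out any 1 gene gave 0.209 to 0.322. The bright and dim changes had the same sign in 8 of the 10 pairs and in 356 of the 394. Compression near the signal ceiling may have shrunk changes of the brightest genes, but shrinkage alone would not turn a sign. Whether the dimmer probe sets report the same transcripts was not tested. The bright pairs also lie further apart in level, and with that gap as a term the difference was -0.308 (-0.554 to -0.0624), or -0.281 (-0.572 to 0.01) over the 6 bright pairs with gaps within the range of the others, so the gap stays open as part of it. The slope test had been set to exclude that abundant transcripts simply changed little, but Th, Dbh and Chga each have 1 probe set and were not in it, so for these genes compression and a small true change cannot be told apart, a limit that also holds for Pnmt and Cyp11a1 at percentiles 99.68 and 99.93.

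Calls that fell outnumbered calls that rose by 1.66 times. Whether scaling each array to a common trimmed mean contributes is not decided. The ratio was 1.229 after quantile normalization and 0.884 after median centring, a range that neither excludes the scaling nor makes it the whole cause. These methods give the arrays equal distributions or equal medians, which can draw the ratio toward 1 also where an excess of falls is true. A difference in RNA integrity is not decided either: the log2 3' over 5' ratio was lower in the immobilized group by the difference -0.174 for Actb, within the pooled SD of 0.176, and -0.0344 for Gapdh, within that of 0.124. The rule written for this test counted a ratio no higher in the immobilized group against RNA degradation there. Both ratios met that rule, but differences within the pooled SD were read as undecided. A true excess of falls after immobilization stays open: the 18 BioB, BioC, BioD and Cre hybridisation controls had a median log2 change of -0.0151 (-0.297 to 0.314), against -0.12 for all tested probe sets, but they differed by medians of 0.23 and -0.40 between arrays of the same group, too much to tell it apart from the scaling.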

How the results depend on the processing

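An offset 4 times the larger of those set beforehand and the omission of probe sets at or above the 99th percentile were chosen after the data were seen. No paired analysis was possible because the labels give the groups no shared replicate numbers. Among the 120 named genes 105 passed the test, all 105 kept their direction in every setting run, and 77 stayed past the threshold in every setting. Of 1550 combinations of these genes with a setting, 68 were no longer past it, most of them without immobilized 1 or immobilized 2. Leaving out each array in turn gave 785 to 2638 probe sets that rose and 893 to 3800 that fell, and with fewer arrays fewer calls follow from the construction only in part, since leaving out unstressed 1 gave the highest counts; the cause was not tested. Lists higher numbered 8 to 14 and lists lower 0 to 1 over the same settings. With 1 probe set per gene 1246 rose and 2463 fell, from fewer tests. At an adjusted p under 0.10, 2801 rose and 4815 fell. No probe set called in the main setting was called in the opposite direction in any of the 14 settings refitted over all probe sets. With an estimated correlation 0 lists were higher, where the preset correlation gave 10; that test also has only 2 degrees of freedom, and for the cAMP, glucocorticoid, inflammatory and cholesterol lists the estimate lay below the preset value, so a larger correlation is not the cause of their loss. Signs reversed only among genes that had not passed the test. Col3a1 was at 0.0103 after median centring. Leaving out each array gave ranges of -0.50 to 0.24 for Col3a1, -0.14 to 0.23 for Pnpla2, -0.30 to 0.32 for Th, -0.15 to 0.33 for Dbh, -0.13 to 0.94 for Hba-a3 and -0.0361 to 0.63 for Alas2. The cause was not tested. Th and Dbh read 68379 and 67779 on immobilized 1 but 44651 and 48705 on immobilized 2, the array with the lowest maximum. The check of equal trimmed means leaves out 2% of values at each end and could not show such a difference between arrays. The folds of dim genes shrink with a larger offset, by construction.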

Other observations

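The gene families of the next 2 paragraphs were chosen by symbol only after the changes of all genes had been seen. Their tests were run after that too, on the same arrays. Such a choice favours small camera p-values and medians outside the ranges of random lists. The adjustment covers only the families chosen. These p-values and ranges therefore describe the chosen families and are not evidence that the families changed. The neighbour test was set before its result was known.

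Of 73 mitochondrial ribosomal protein genes, which serve translation inside mitochondria, 34 fell and 1 rose, with a median log2 change of -0.43 (camera adjusted p = 5.77e-05 over the 7 families, and adjusted p = 0.396 with an estimated correlation). Random lists of the same size and level had medians of -0.23 to 0.01 (95% range). Mrps31 changed by -1.59, Mrpl50 by -1.43 and Mrpl34 by -1.24, and after median centring 24 fell and 2 rose. Without immobilized 1 the family had 10 falls and 2 rises, without immobilized 2 it had 7 and 0, and without unstressed 2 it had 27 and 2. The cytosolic ribosomal protein genes had no call in either direction in the main setting. Rpl21 rose after quantile normalization, after median centring and without probe sets at or above the 99th percentile of level. Of 185 Zfp zinc finger genes 57 fell and 10 rose, with a median of -0.44 against -0.30 to -0.10 in random lists (camera adjusted p = 0.00725, and adjusted p = 0.345 with an estimated correlation). The falls and rises were 45 and 13 (median -0.31) after quantile normalization and 42 and 16 (median -0.30) after median centring. They were 52 and 17 without unstressed 1, 17 and 5 without immobilized 1, and 14 and 4 without immobilized 2. Of 13 peroxins, which build peroxisomes, 7 fell and 1 rose (median -0.86 against -0.53 to 0.20 in random lists, camera adjusted p = 0.0259, and adjusted p = 0.234 with an estimated correlation). Their median was -0.56 after quantile normalization, with 6 falls, and -0.72 after median centring, with 7. Of 10 Hox transcription factor genes 7 fell and 1 rose (median -0.75 against -0.59 to 0.23 in random lists, camera adjusted p = 0.0415, and adjusted p = 0.234 with an estimated correlation), with Hoxd4 at -2.24 and Hoxa5 at 1.52, a call lost without immobilized 2 (adjusted p = 0.0597 in limma). After median centring 5 of the Hox genes fell and 1 rose (median -0.60), and after quantile normalization 6 fell and 1 rose (median -0.65). Leaving out immobilized 1 gave 5 peroxin and 3 Hox falls with 0 and 1 rises, and leaving out immobilized 2 gave 3 and 2 falls with 0 rises.

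In 3 other families most calls were rises. Of 8 tubulin genes, the subunits of microtubules, 5 rose and 0 fell (median 0.69, camera adjusted p = 5.36e-05, and adjusted p = 0.234 with an estimated correlation), with Tubb6 at 3.59 and Tuba4a at 2.20. Of 7 Adamts protease genes 4 rose and 0 fell (median 1.02, camera adjusted p = 6.97e-04, and adjusted p = 0.234 with an estimated correlation), with Adamts9 at 3.37 and Adamts1 at 2.89. Of 16 amino acid transporter genes of the Slc7, Slc3 and Slc38 families 6 rose and 1 fell (median 0.36, camera adjusted p = 0.00475, and adjusted p = 0.234 with an estimated correlation). Slc7a5, a carrier of large neutral amino acids, rose by 2.33 and Slc7a11, the cystine carrier, by 2.26. The transporters had 3 rises and 0 falls without immobilized 1 and 4 and 0 without immobilized 2. The directions of these medians were the same after quantile normalization and median centring.

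Iqub, whose product is known from cilia, rose by 7.27 from unstressed readings not shown to lie above background (45.7 and 68.4), and it lies next to Ndufa5 in the GRCr8 gene table. Ndufa5 was the only 1 of 28 oxidative phosphorylation genes that rose. Over 5756 pairs of neighbouring genes, both rose in 107 pairs against a mean of 69.4 in shuffles, a ratio of 1.54 (one-sided permutation p = 1e-04, the smallest that 10000 shuffles can give), and without pairs sharing a symbol stem the ratio was 1.48 (one-sided permutation p = 1e-04). Both fell in 358 pairs against 297 (ratio 1.2, one-sided permutation p = 2e-04), so neighbours moved together in either direction. A shared response of neighbouring genes may thus link such pairs, among them Giot1 at 4.76 beside Vom2r53 at 5.0, but transcripts that run on into the next gene, or probe sets that report on the neighbour, were not tested, and the test covers all pairs and does not settle any single one.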
